A study of Rattus norvegicus with 36 samples.

How the data were processed

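RNA was sequenced from the nucleus accumbens of 9 Sprague-Dawley rats that had gone through conditioned place preference, a procedure in which an animal learns to link one compartment with a drug. The animals were 8 weeks old, per the labels. They formed 3 groups of 3 rats. Saline rats received physiological serum throughout. CPPE rats received cocaine and expressed a preference for the cocaine-paired compartment, and nCPPE rats received the same cocaine treatment without expressing it. The labels also call the CPPE and nCPPE rats dependent and non-dependent. Treatment was 4 injections, 15 days of withdrawal and a final injection of cocaine (5 mg/kg) or serum, followed at once by an 18 min preference test. The series text also gives an extinction phase of 12 days. The dose of the conditioning injections, the criterion that parted CPPE from nCPPE rats and the sex of the animals are not given in the sources used here. The labels name the nucleus accumbens as the tissue of every library, while their extraction protocol speaks of RNA from both the nucleus accumbens and the caudate putamen.

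Per the labels' protocols, polyadenylated RNA was selected from 300 ng of total RNA and turned into libraries with a strand-specific kit (TruSeq Stranded mRNA). Per the submitters' processing notes, bcl2fastq 2.18.0.12, STAR and HTSeq 0.5.3 were used. The STAR version, the genome build, the annotation release and the strand setting of the counting are not given in the sources used here. The deposited values are raw read counts per Ensembl gene, whole numbers with no normalization, in 1 file for each of 4 technical replicates of each rat, 36 files in all. Each file listed the same 32402 gene identifiers, with no row for unassigned reads. Because the strand setting is not stated, genes that overlap another gene carry uncertain counts. Genes with near-identical copies also carry uncertain counts, whatever the strand setting.

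The files give identifiers without gene names. The reference table used here for names (assembly GRCr8) held no Ensembl identifiers, so 0 of them could be paired with a symbol. Genes are therefore given by identifier. For the same reason 38 gene lists fixed before the data were examined were not tested. They covered immediate early genes, markers of medium spiny neurons and of other cell types, dopamine signalling, receptors, matrix, chromatin enzymes, stress, clock, energy and immune genes. No list contributes a value to the report.

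Technical replicates of a rat were compared with a chi-square test over genes with at least 40 counts in the 4 together. The statistic per degree of freedom was between 1.00 and 1.02 in every rat, and 4.91% to 5.38% of genes had p below 0.05, which is what counting noise alone gives. The 4 technical replicates differed by no more than sampling noise and were summed, so that each rat counted as 1 sample. Totals were 6771828 to 9961469 counts per technical replicate and 27724289 to 39067715 per rat.

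Differences between groups were tested with edgeR 4.0.16 in R 4.3.3. Low-count genes were removed with filterByExpr, which left 15555 genes, and libraries were scaled with TMM (trimmed mean of M values). Negative binomial dispersions and quasi-likelihood F-tests (glmQLFit, glmQLFTest) were fitted with group as the sole factor over all 9 rats, so that the groups shared an estimate of the spread. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called changed at an adjusted p below 0.05. The 4 contrasts were CPPE against nCPPE, CPPE against Saline, nCPPE against Saline, and the mean of both cocaine groups against Saline. Standard errors and 95% intervals of log2 fold changes came from the same fits and used the shared spread. Where the Saline rats spread more than the others, the intervals are too narrow against Saline and too wide between the cocaine groups. CPM values are counts scaled to a common library total, the usual counts-per-million scale, with TMM-scaled library sizes. Separation of the groups was measured as a PERMANOVA pseudo-F on Euclidean distances of log2 CPM (prior count 2), with an exact one-sided permutation p over all 280 splits of the rats into groups of 3.

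The rule for single genes, fixed before the data were examined, took genes past the threshold whose groups did not overlap. Because fewer than 5 passed in each comparison, it fell back on genes with a mean of at least 1 CPM and the smallest unadjusted p in each direction. As the identifiers carry no names, the first 2 in each direction are given in place of 5. These genes did not pass the test.

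The edgeR procedure was tested on simulated counts with 200 genes changed by 1.5-, 2- or 4-fold, drawn with the dispersions of all 9 rats. Every simulated rat was given the same spread, so that of Saline 2 was also laid on the cocaine rats. At 4-fold, 86.4% of the changed genes were recovered for CPPE against nCPPE, 84.8% for CPPE against Saline, 83.3% for nCPPE against Saline and 95.5% for cocaine against Saline. At 2-fold the shares were 20.9%, 20.9%, 16.4% and 49.3%. At 1.5-fold they were at most 1.49%. With the dispersions of the 8 rats other than Saline 2, the shares at 2-fold were 83.6%, 73.1%, 88.1% and 91.0%, and those at 1.5-fold 62.7%, 46.3%, 56.7% and 56.7%. These simulated sets held only the 8 rats, so their shares do not describe the fit of all 9 rats.

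Comparisons of CPPE and of nCPPE with Saline share the same controls. The correlation of their fold changes was set beside 20 simulated sets in which all rats, Saline included, were drawn without a group difference. A first simulation gave each gene a single dispersion over all rats. After its result was seen, a second was added with separate dispersions for Saline and cocaine rats, since the spread proved to be concentrated in the Saline group. Both are reported.

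Alternatives fixed before the data were examined were DESeq2 1.42.0, limma-voom with sample quality weights (limma 3.58.1), RLE and upper-quartile scaling, no filter and a stricter filter on low counts (above 1 CPM in at least 3 rats), robust dispersions, fits of the compared groups alone, rat number as a block, an adjusted p below 0.1, a surrogate variable (sva 3.50.0), technical replicate a alone, and leaving out each rat in turn. DESeq2, limma-voom and the 500 most variable genes with Saline 2 left out were added after seeing the data. Other splits of the rats into groups of the same sizes were refitted to see how often they gave as many calls. Counting intervals were not computed, since every value rests on replicate animals.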

Results

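The series measured messenger RNA in the nucleus accumbens, a ventral part of the striatum that is a main target of midbrain dopamine neurons, in rats after cocaine place conditioning, extinction and a reinstating injection. It asked how animals that expressed the conditioned preference (CPPE) differed from animals with the same cocaine treatment that did not express it (nCPPE), and how both differed from Saline controls. Each group held 3 rats. Summed over 4 technical replicates, the Saline rats had 28933896, 29142265 and 27724289 counts, the CPPE rats 31891710, 39067715 and 29654851, and the nCPPE rats 33715494, 30622693 and 31152594. Of 32402 listed genes, 10009 had no count in any rat. Between 18351 and 19319 genes had at least 1 count in a given rat.

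The accumbens transcriptomes of 8 of the 9 rats were close to each other whatever their group. Pearson's r of log2 CPM across the 15555 tested genes was 0.982 to 0.993 between any pair of these 8 rats, with a median of 0.989 both within and between groups. The ninth, Saline 2, stood apart. Its r with the other rats was 0.919 to 0.940, and 4374 genes lay over 2-fold from the mean of the other rats, 1347 of them higher and 3027 lower. In the other rats that number was between 154 (nCPPE 1) and 385 (nCPPE 3). Saline 2 also had the fewest genes detected, 18351 against at least 19023 elsewhere, and its 10 most abundant genes took 12.0% of its counts against 14.1% to 18.7% in the other rats. Its sequencing depth, 29142265 counts, was within the range of the others. These correlations are across genes, which are not independent replicates.

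**Figure D1:**
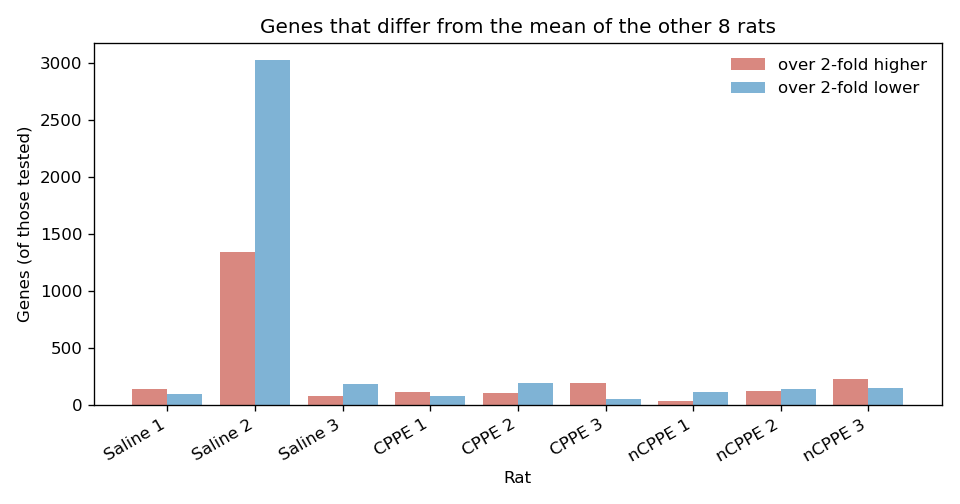
Number of tested genes (y axis) over 2-fold higher (red bars) or lower (blue bars) in each rat (x axis) than in the mean of the other 8 rats, out of 15555. Saline 2 had 1347 higher and 3027 lower, while the totals of the other rats were 154 to 385.

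The 3 groups did not separate from each other. The first principal component held 64.9% of the variance and parted Saline 2, at a score of 116.0, from the other rats, at -24.8 to -2.11. The pseudo-F for group was 0.685, with groups accounting for 18.6% of the squared distances (exact permutation p = 0.986, one-sided, 280 splits, smallest possible p 0.00357). Without Saline 2 the exact permutation p was 0.55. In that analysis the first component (29.6% of the variance) ran from CPPE 2 (-26.3) and nCPPE 3 (-23.0) at one end to nCPPE 2 (30.1) at the other, and so crossed the cocaine groups. Saline 1 and Saline 3 lay next to each other, at -8.40 and -6.53.

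**Figure D2:**
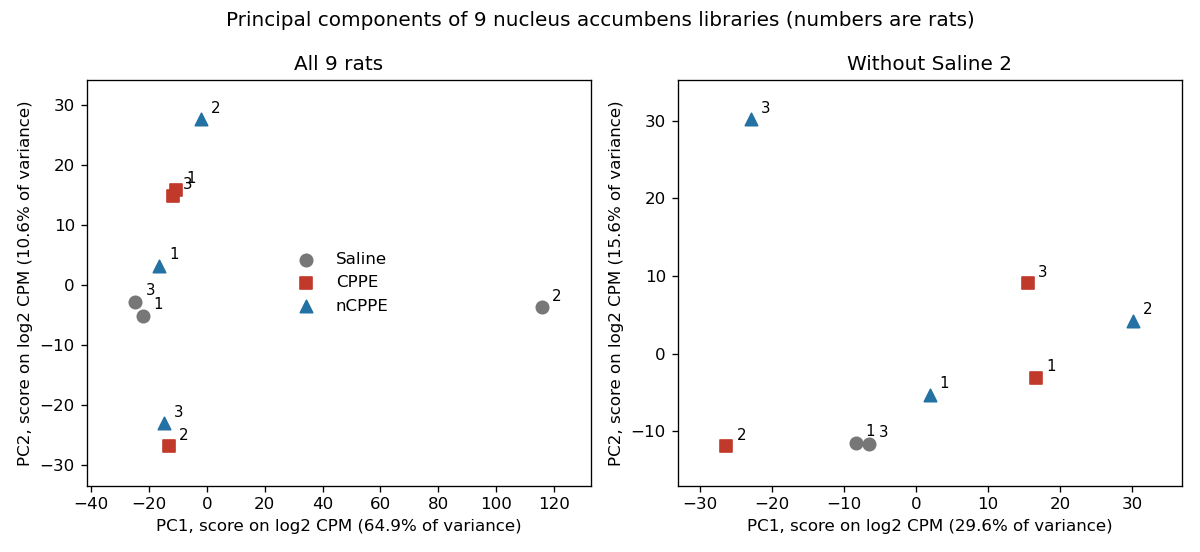
Scores of each rat on the first (x axis) and second (y axis) principal components of log2 CPM, for all 9 rats (left) and without Saline 2 (right). Grey circles are Saline, red squares CPPE and blue triangles nCPPE, with the rat number beside each point. Saline 2 scored 116.0 on the first component on the left, and on the right CPPE and nCPPE rats lay at both ends of it.

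The comparison of CPPE with nCPPE rats asked which genes went with expressing the preference at equal cocaine exposure. edgeR called no gene changed, and DESeq2 called 2. The gene with the smallest p, ENSRNOG00000016164, averaged 6.14 ± 1.23 CPM in CPPE and 0.451 ± 0.267 CPM in nCPPE rats (SD, n = 3 each), a log2 difference of 3.75 ± 0.73 (SE), and every CPPE rat was above every nCPPE rat. Saline rats had both levels of this gene, with 0.831 CPM in Saline 1, 6.63 CPM in Saline 2 and 7.02 CPM in Saline 3. ENSRNOG00000045924 was at 1.57 ± 0.310 CPM in CPPE and 0.703 ± 0.161 CPM in nCPPE rats. In the other direction, ENSRNOG00000016957 averaged 2.03 ± 0.167 CPM in CPPE and 10.2 ± 12.2 CPM in nCPPE rats, a mean set by nCPPE 3 with 24.3 CPM beside 2.86 and 3.42 CPM in the other rats of that group. ENSRNOG00000060161 had 8.61 CPM in the same rat, nCPPE 3, and 0.381 to 0.720 CPM in all others.

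In edgeR's quasi-likelihood test 0 of 15555 genes had an adjusted p below 0.05 for CPPE against nCPPE. By the same test 84 (0.540%) had an unadjusted p below 0.05, under the share of 0.05 that chance gives. The shared spread of this fit includes Saline 2. ENSRNOG00000016164 had an unadjusted p of 0.000877 in this genome-wide edgeR fit and an adjusted p of 1.0. With only the CPPE and nCPPE rats in the edgeR fit, its log2 difference was again 3.75, its adjusted p was 0.0510, and 433 genes had an unadjusted p below 0.05. DESeq2 called 2 genes, both higher in CPPE. They were ENSRNOG00000016164, with an adjusted p of 0.000541 (range over the 23 alternatives for this gene 0.000541 to 1.0), and ENSRNOG00000029386, named after its values were seen. The latter had 79, 248 and 52 counts in the CPPE rats, 0 in all nCPPE rats, and 77, 0 and 0 in the Saline rats. Its edgeR adjusted p was 1.0. limma-voom with quality weights called 0 genes (640 at an unadjusted p below 0.05). Without Saline 2, which enters this fit through the shared spread, edgeR called 0 genes and 556 had an unadjusted p below 0.05. DESeq2 then called 1, ENSRNOG00000031065, which also falls outside the naming rule, with 44, 65 and 39 counts in CPPE and 5, 5 and 7 in nCPPE rats. The Saline rats had 46, 2 and 9 counts of it, Saline 1 being at the level of the CPPE rats. In that DESeq2 fit ENSRNOG00000016164 kept its log2 difference (3.77, beside 3.76 with all rats) at an adjusted p of 0.0562.

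For most genes the data bounded the size of any difference between CPPE and nCPPE. Of 13767 genes with a mean of at least 1 CPM, the 95% interval excluded a 2-fold difference in either direction for 11587 (84.2%), and a 4-fold difference for 13611 (98.9%). CPPE and nCPPE rats did not overlap for 1321 of the tested genes (8.49%, where chance gives 10%). Smaller changes were recovered poorly in simulated data that gave every rat the spread over all 9 rats. There 1.49% of 67 genes changed by 1.5-fold were recovered in this comparison. With the spread of the rats other than Saline 2 that share was 62.7%. The first share lays the spread of Saline 2 on the CPPE and nCPPE rats, so it is not the resolution of the real comparison. The second share comes from a fit without Saline 2, while the reported test keeps that rat in its shared spread. The second share is therefore not the resolution of the reported test either.

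The comparison of CPPE with Saline rats asked what cocaine conditioning and the reinstating injection left in animals that expressed the preference. Neither edgeR nor DESeq2 called a gene changed with all rats. ENSRNOG00000008118 averaged 5.74 ± 0.714 CPM in CPPE and 2.20 ± 0.634 CPM in Saline rats (SD, n = 3 each), with a log2 difference of 1.38 ± 0.32 (SE). ENSRNOG00000021285 was at 19.4 ± 0.832 CPM against 13.0 ± 0.590 CPM, a log2 difference of 0.58 ± 0.15. Of those lower in CPPE, ENSRNOG00000030530 had 1.25 ± 0.0630 CPM against 2.49 ± 0.362 CPM, and ENSRNOG00000018426 had 9.99 ± 1.60 CPM against 16.5 ± 3.55 CPM. In each of these genes the 3 CPPE rats lay on one side of the 3 Saline rats.

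For CPPE against Saline, edgeR called 0 of 15555 genes (smallest adjusted p 0.882), with 139 (0.894%) at an unadjusted p below 0.05, and DESeq2 and limma-voom each called 0 (182 and 1154 at an unadjusted p below 0.05). The edgeR adjusted p of all the named genes in this comparison was 0.882. Saline 2 held much of the spread, with a biological coefficient of variation of 26.2% over all rats and 11.8% without it. With Saline 2 left out edgeR again called 0 genes, 929 had an unadjusted p below 0.05, and DESeq2 called 12 (5 higher, 7 lower). Without Saline 1 or Saline 3 edgeR also called 0, with 488 and 832 genes at an unadjusted p below 0.05. The 95% interval excluded a 2-fold difference for 10113 of 13767 genes (73.5%). This share, like those of the other comparisons with Saline, may be too high, since the intervals use the shared spread. Groups did not overlap for 890 genes (5.72%, where chance gives 10%).

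The comparison of nCPPE with Saline rats asked the same of animals that received cocaine without expressing the preference. edgeR called no gene changed, and DESeq2 called 2. ENSRNOG00000008118 was again among the genes with the smallest p, at 6.10 ± 2.46 CPM in nCPPE against 2.20 ± 0.634 CPM in Saline rats (SD, n = 3 each), a log2 difference of 1.47 ± 0.32 (SE). The Saline values are the same as in the comparison with CPPE, so the 2 results for this gene are not independent. ENSRNOG00000016275 had 27.8, 21.4 and 15.3 CPM in the nCPPE rats, and 2.53, 0 and 0 CPM in the Saline rats. CPPE rats had between 0.431 and 4.61 CPM of this gene. Its fitted log2 difference was 4.65 ± 1.23, and the Saline mean rested on Saline 1 alone. Of those lower in nCPPE, ENSRNOG00000016164 was at 0.451 ± 0.267 CPM against 4.83 ± 3.47 CPM in Saline, and ENSRNOG00000046663 at 1.65 ± 0.449 CPM against 3.65 ± 0.887 CPM.

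For nCPPE against Saline, edgeR called 0 of 15555 genes (smallest adjusted p 0.937), with 179 (1.15%) at an unadjusted p below 0.05. limma-voom called 0 (1221 at an unadjusted p below 0.05). DESeq2 called 2, both lower in nCPPE, and these were ENSRNOG00000016164 (log2 difference -3.42, adjusted p 0.00797, range 0.00797 to 1.0 over the 22 alternatives that give it an adjusted p, of which DESeq2 without Saline 2 is not one) and ENSRNOG00000029386, whose sole Saline counts were 77 in Saline 1. Without Saline 2 edgeR called 0 genes, 964 had an unadjusted p below 0.05, and DESeq2 called 15 (4 higher, 11 lower). edgeR also called 0 without Saline 1, Saline 3 or nCPPE 1, with 377, 552 and 109 genes at an unadjusted p below 0.05. The 95% interval excluded a 2-fold difference for 10355 of 13767 genes (75.2%), and groups did not overlap for 626 genes (4.02%, where chance gives 10%).

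**Figure D3:**
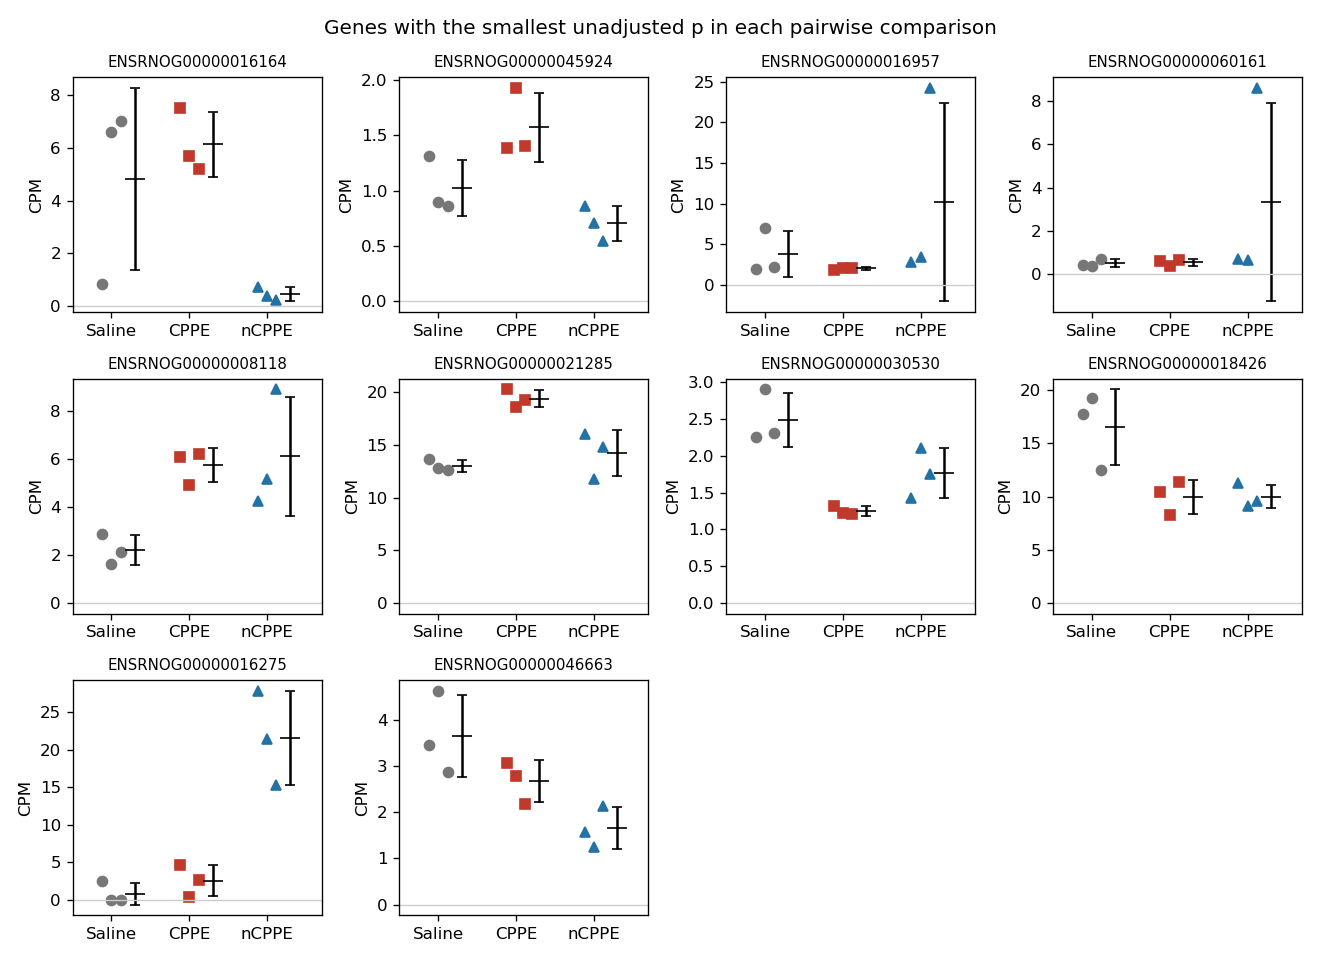
CPM (y axis, linear) of the genes with the smallest unadjusted p in the pairwise comparisons, by group (x axis). Points are rats 1 to 3 from left to right in each group, and the bar beside them is the mean ± SD (n = 3). None passed edgeR's adjusted threshold, and ENSRNOG00000016164 took both a low value (0.831 CPM) and high values (6.63 and 7.02 CPM) among Saline rats.

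Taking both cocaine groups as 6 rats against the 3 Saline rats asked for what cocaine exposure left whatever the preference. ENSRNOG00000008118 averaged 5.92 ± 1.63 CPM in the cocaine rats (SD, n = 6) and 2.20 ± 0.634 CPM in Saline rats (SD, n = 3), a log2 difference of 1.42 ± 0.28 (SE), with all 6 cocaine rats above all Saline rats. For this gene these are the values already used in the pairwise comparisons with Saline, not a further observation. ENSRNOG00000046195 was at 1.84 to 2.51 CPM in the cocaine rats against 1.21 to 1.48 CPM in Saline rats, a log2 difference of 0.70 ± 0.19 and also without overlap. ENSRNOG00000018426 was at 9.99 ± 1.23 CPM in cocaine rats against 16.5 ± 3.55 CPM in Saline, without overlap. ENSRNOG00000005826 was at 0.851 ± 0.442 CPM against 5.90 ± 5.64 CPM, with Saline 1 (0.588 CPM) inside the range of the cocaine rats. Its Saline mean rested on Saline 2 (11.8 CPM) and Saline 3 (5.29 CPM). The log2 difference was -2.80 with all rats, -1.79 without Saline 2 and -1.03 by limma-voom with quality weights.

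For cocaine against Saline, edgeR called 0 of 15555 genes (smallest adjusted p 0.825), with 193 (1.24%) at an unadjusted p below 0.05, and limma-voom called 0 (1410 at an unadjusted p below 0.05). DESeq2 called ENSRNOG00000008118 alone, with an adjusted p of 0.0425 (range 0.0425 to 1.0 over the 21 alternatives that give it an adjusted p, of which DESeq2 without Saline 2 is not one). Without Saline 2 edgeR called 0 genes, 1055 had an unadjusted p below 0.05, and DESeq2 called 27 (6 higher, 21 lower). edgeR likewise called 0 without Saline 1, Saline 3 or nCPPE 1, with 899, 1324 and 126 genes at an unadjusted p below 0.05. The 95% interval excluded a 2-fold difference for 11149 of 13767 genes (81.0%). Groups did not overlap for 160 genes (1.03%, where chance gives 2.38%).

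Fold changes of CPPE and of nCPPE rats against Saline went together across genes, as shared controls alone make them do. Pearson's r over 15555 genes was 0.682, the covariance 0.0699, and 84.1% of genes had the same sign. Simulated sets drew all rats anew, Saline included, without a group difference. With a single dispersion per gene they gave a mean r of 0.508 (0.483 to 0.527), a covariance of 0.0663 (0.0621 to 0.0696) and the same sign in 66.9% of genes. With separate dispersions for Saline and cocaine rats they gave an r of 0.828 (0.819 to 0.838), a covariance of 0.139 (0.133 to 0.145) and the same sign in 84.6% of genes. The observed r and covariance lay above the first simulation and below the second. Neither simulation reproduced these controls. Both drew genes independently and gave the Saline rats a common dispersion per gene, whereas in the data Saline 2 alone stood apart. Their narrow ranges therefore do not decide on the observed values. Without Saline 2, r was 0.653 and the covariance 0.0680, beside 0.623 (0.579 to 0.657) and 0.0492 (0.0429 to 0.0567) in simulated unchanged groups. The same sign was found in 73.3% of genes, beside 70.8% in the simulated groups. Here the observed r lay inside the simulated range and the covariance above it. Genes were drawn independently in these sets too, so their ranges do not decide either. The 3 controls cannot be split into 2 sets of at least 2 rats, and whether the fold changes went together beyond what shared controls give was not settled. edgeR made no calls in either comparison. With all rats DESeq2 called 0 genes for CPPE against Saline, so its calls could not overlap. The overlap of DESeq2 calls without Saline 2 was not counted.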

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

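The tests of sequencing depth, abundant genes, technical replicates, dilution and a shared gradient were chosen only after Saline 2 had been seen to stand apart, and so was the choice to look for extreme values over both cocaine groups as 6 rats.

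Among the 6 cocaine rats, 9 measures were examined for a rat far from the rest, and chance marks about 1 in 20 of such groups. ENSRNOG00000005826 was at 1.73 CPM in CPPE 2, while the other cocaine rats had 0.510 to 0.831 CPM, and the gap took 0.736 of the whole range. The Saline rats had 0.588, 11.8 and 5.29 CPM of the same gene.

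Saline 2 differed from the other rats over a large part of the transcriptome. Depth was argued against, since 2 rats had no more counts than Saline 2 and at most 265 genes over 2-fold from the mean of the others, beside its 4374. A few abundant genes were argued against, since the share of counts outside the 50 most abundant genes differed by at most 1.08-fold between Saline 2 and any other rat, too little to move other genes by 2-fold. The least distant of its technical replicates had 3581, beside at most 243, so a fault in the sequencing of a single technical replicate does not account for the pattern. Dilution of the usual tissue by other tissue of up to 4-fold was argued against for the strongest falls, since 144 of 11274 genes (1.28%) with a mean of at least 5 CPM in the other rats were over 8-fold lower in Saline 2, beside at most 2 in any other rat.

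Of the explanations examined for Saline 2, a gradient of the dissection, RNA quality and another tissue in this animal's sample stay open. A fault shared by all technical replicates of this rat, such as one in library preparation, was not tested and also stays open. These replicates differed by no more than sampling noise, so comparing them cannot address such a fault. The loading of the first component of the other 8 rats correlated with the deviation of Saline 2 across genes at an absolute r of 0.186 (Spearman 0.216), between the values set for and against a shared gradient. RNA quality and another tissue cannot be told apart here. The reference for names held no Ensembl identifiers, so 0% of the identifiers could be matched to a name or to a cell type marker. The extraction protocol's mention of the caudate putamen makes another striatal sample a possible explanation that was not tested. No biological explanation was tested, since the design gives the Saline rats no difference from each other.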

How the results depend on the processing

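The DESeq2 and limma-voom fits and the group separation of the 500 most variable genes with Saline 2 left out were chosen after seeing the data. Of 91 alternative gene counts, 84 were 0. DESeq2 gave 2 genes for CPPE against nCPPE, 2 for nCPPE against Saline and 1 for cocaine against Saline, and with Saline 2 left out 1, 15 and 27, and 12 for CPPE against Saline. The cause was not tested. limma-voom with Saline 2 left out called 0 in all 4 comparisons, with 565, 1340, 1447 and 1675 genes at an unadjusted p below 0.05. edgeR called 0 with each rat left out. The genes at an unadjusted p below 0.05, 84, 139, 179 and 193 with all rats, numbered 82, 488, 377 and 899 without Saline 1, 556, 929, 964 and 1055 without Saline 2, and 89, 832, 552 and 1324 without Saline 3. With a surrogate variable they numbered 570, 580, 419 and 486, and with only the groups compared 433, 85 and 89 in the 3 pairwise comparisons. With limma-voom quality weights they numbered 640, 1154, 1221 and 1410. Each of these fits gave 0 calls. The surrogate variable was -0.933 in Saline 2 and 0.0214 to 0.196 in the other rats. limma-voom with all rats gave Saline 2 a quality weight of 0.0300, beside 0.742 to 2.96 in the others. Both fits thus mainly set Saline 2 aside and are not checks independent of leaving it out. In the limma-voom fits and in edgeR without Saline 2, each comparison with Saline lay above the share of 0.05 that chance gives. CPPE against nCPPE lay below it. Genes are not independent replicates, so such counts do not decide on an effect. Of 352 single-gene alternatives with an adjusted p, 349 kept their direction and stayed short of the threshold, 3 (by DESeq2) passed it and 0 reversed. DESeq2, with or without Saline 2, gave no adjusted p in 10 others. Part of this tally could not change direction. The threshold of 0.1 reuses the main fit, and leaving out a rat outside the comparison hardly moves a fold change. The genes were also picked by their smallest p in the same data. No pairing by rat number was seen. Same-numbered rats correlated at -0.447 to 0.257 in their deviations from the group mean. Of 9 rats, 2 had their highest correlation with a rat of their own number. A pairing is not excluded, since the deviations of 3 rats from their own mean depend on each other. With the replicate block edgeR called 0 genes in each of the 4 comparisons, and the correlation of fold changes was 0.676. That correlation was 0.555 with no filter on low counts (the cause was not tested) and 0.580 to 0.835 with single rats left out, highest without Saline 1 or Saline 3. The exact permutation p for group separation was 0.943 to 0.986 over the other settings with all rats, 0.282 to 0.989 with single rats left out, and 0.55 for the 500 most variable genes without Saline 2. Scaling moved the median of all genes by under 0.02 on the log2 scale. The planned tests of gene lists were not run, since the identifiers could not be named. Simulations that gave every rat the spread over all rats recovered 16.4% to 49.3% of 2-fold changes. With Saline 2 left out of both the spread and the fit they recovered 73.1% to 91.0%, which does not describe the fits of all rats.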

Other observations

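The refits of other splits of the rats were chosen only after the counts of changed genes had been seen. The pairs of rats described here were refitted after the count for cocaine against Saline without Saline 2 had been seen.

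Because the real groups gave 0 calls, every split gives as many, and the number of calls cannot decide on chance. For CPPE against nCPPE, CPPE against Saline and nCPPE against Saline the real split gave 0 genes, and so did every other of the 10 splits of the 6 rats, which are too few for a share under 0.05. At an unadjusted p below 0.05 the real splits gave 84, 139 and 179 genes, and the others 58 to 450, 239 to 845 and 150 to 1019. For CPPE against Saline the real split thus gave fewer such genes than every other split. For cocaine against Saline the real split gave 0 genes and the highest of the other 83 gave 2, so that all 84 splits counted as giving as many. At an unadjusted p below 0.05 that comparison gave 193 genes and the other splits 67 to 2190.

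With Saline 2 left out, Saline 1 and Saline 3 set against the 6 cocaine rats in a fit of 2 groups gave 1113 genes at an unadjusted p below 0.05 and 0 calls by edgeR. A chance choice of rats is not excluded, since 3 of the 28 pairs of these 8 rats, Saline 1 and Saline 3 included, gave as many. The pair of CPPE 2 and nCPPE 3 gave the most, 2890 genes and 113 calls. These rats come from different cocaine groups. The pair was picked as the highest of the 28, and no chance value for such a maximum was computed. It does not by itself show a structure of the samples. Without Saline 2 these rats lay near each other on the first component (-26.3 and -23.0), which comes from the same data, and far apart on the second (-12.0 and 30.2). Why this pair gave the most was not tested.

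A search for genes near absent in some rats and well expressed in the rest was made under 12 definitions and found between 0 and 86 genes. The definition set first, at most 3 counts or at least 100 counts in every rat, found 0, and the pattern was not pursued.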
